A study of Prunus sibirica with 6 samples.

How the data were processed

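RNA-seq libraries of flower buds of Prunus sibirica at the labelled microspore stage were analysed, 3 from a male sterile and 3 from a male fertile clone. Per the labels' protocols, buds were ground under liquid nitrogen, total RNA was extracted with a kit and libraries were made by standard Illumina protocols. CASAVA, Bowtie2 and RSEM are named in the submitters' processing notes, without versions or roles. The assembler, read filters, genome build and test behind the authors' fold changes are not given in the sources used here. The labels call the samples biological replicates, and do not say whether they came from separate trees. Each group is 1 clone.

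Estimated counts of reads per cluster, which need not be whole, were deposited by the authors for transcription factors and other regulators only, per the file headers, in 1625 entries for 1508 clusters. The 114 clusters listed under more than 1 family had identical values and were used once. FPKM values of the same clusters, and of 34377 clusters in a second table, were also deposited, per the file headers. Both tables held the same FPKM for the 1508 shared clusters. Cluster length in bases, annotation hits, a log2 fold change and a q-value of the authors' comparison stand in the regulator table, per the file headers. Between 78.2% and 84.7% of the estimated counts of a library were whole within 0.005. RSEM-type counts divide reads that match several clusters, so clusters of close paralogs or of alleles of 1 locus may share reads.

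Groups and replicate numbers came from the sample labels. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr removed 128 clusters holding 0.0424% of the counts, TMM scaled the libraries within the regulator table, and glmQLFit (robust) with glmQLFTest gave p-values, adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are sterile over fertile, and standard errors were derived from the fold change and its F statistic. The FPKM table was tested with limma 3.58.1 (trend, robust) on log2(FPKM + 1), for clusters with FPKM of at least 1 in at least 3 libraries. On this scale fold changes of low clusters are understated. Families with at least 5 tested clusters and gene lists with at least 3 were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The 16 lists were matched by name patterns in the NR, Swiss-Prot and NT descriptions, and 14 were large enough to test. Library depth was estimated by robust regression of count over FPKM on cluster length, over clusters with FPKM of at least 5 and at least 50 counts, and came to 24.1, 25.3 and 22.1 M fragments for the fertile and 16.2, 17.6 and 19.0 M for the sterile libraries. For a cluster of median length (2142 bases) 3 counts correspond to 0.0554 to 0.0864 FPKM.

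Before the data were examined, the groups, tests, lists, alternatives and the rule for named genes were fixed. Named were the 10 clusters with the largest and the 10 with the smallest log2 fold change past the threshold, with mean FPKM of at least 1 in a group, no overlap between groups and an annotated name. Up to 4 members of each list and 2 of each of the 3 leading families by p, all tapetum and floral identity members (up to 12 per list), and 2 unnamed identifiers each way, with a mean FPKM of at least 1 in both groups, were added. MYC2, MYC4, bHLH13, MYB2, MYB62 and the second SVP cluster were chosen after their values were seen. The second ERF5 cluster and the ERF003, MYB35 and MYB80 clusters below the low-count filter were also outside the rule. Where a cluster had 0 counts in a group, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% binomial interval. Floors and intervals cover counting error only.

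Alternatives were other library scales (DESeq2 size factors, table totals, implied whole-library totals with and without median ratios from the FPKM table), DESeq2 1.42.0, no low-count filter, a fold minimum, pseudocounts of 0.1 and 5, other scalings of FPKM, a replicate block and leaving out each library. On counts simulated for the regulator table with 200 changed clusters of 1372, edgeR recovered 82.5%, 98.6% and 100% of changes of log2 0.5, 1 and 2, and 4.06% of its calls were false. On simulated values for the FPKM table, with 200 changed of 21730 clusters, limma recovered 37.0%, 81.5% and 87.7%, and 3.68% of its calls were false. Both simulations changed a smaller share of clusters than was called in the data (57.0% of regulators, 49.8% of the FPKM table), in random directions. Their rates therefore do not cover errors of library scale in the real comparison. Named sets of unnamed clusters, coordinates and sequence variants were not analysed here.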

Results

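The data were RNA-seq profiles of flower buds of Siberian apricot (Prunus sibirica) at the microspore stage, from 1 male sterile and 1 male fertile clone with 3 bud samples each. A clone here is a set of genetically identical trees, so sterility and every other genetic difference between these clones were compared together. Reads had been assembled into transcript clusters. A table of 1508 clusters annotated as transcription factors or other transcriptional regulators held estimated read counts and FPKM (fragments scaled by cluster length and library size), and a second table held FPKM of 34377 clusters with no names. The count totals of the regulator table were 1286368, 1424835 and 1242099 in the fertile libraries and 957196, 1039123 and 1122298 in the sterile libraries. The depth that its counts, lengths and FPKM implied for whole libraries ran from 16.2 M fragments in sterile replicate 1 to 25.3 M in fertile replicate 2. Regulators took 5.34% to 5.64% of the implied total in the fertile libraries and 5.89% to 5.91% in the sterile ones. Across 21730 expressed clusters, log2 FPKM correlated at r = 0.978 to 0.987 within a clone and at 0.888 to 0.895 between clones. The first principal component took 80.1% of the variance. In the regulator counts no pair of libraries agreed within sampling noise. The chi-square per degree of freedom was 1.58 to 11.7 within a clone and at least 47.7 between clones. Cluster positions are not given, because the clusters come from assembled transcripts and no genome build is given in the sources used here.

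The comparison of sterile with fertile buds asked which genes differ between a male sterile and a male fertile clone at the same labelled stage. The sterile buds had far less RNA of the jasmonate repressor TIFY 5A and of the defence regulator WRKY70, and far more of the late anther regulator MALE STERILITY 1 and of the LOB-domain genes AS2, LBD2 and LBD22. ASYMMETRIC LEAVES 2 (AS2, Cluster-6671.21100), a LOB-domain factor of leaf polarity, stood at 51.2 ± 2.76 FPKM in sterile and 0.88 ± 0.181 in fertile buds (mean ± SD, n = 3 each). By edgeR's fit to the counts, which are scaled otherwise than FPKM, the difference was 52.8-fold. MYB20 (Cluster-6671.4513), a factor of secondary wall and phenylpropanoid genes, stood at 47.8 ± 4.15 against 2.21 ± 0.189 FPKM, and LBD22 (Cluster-6671.17447) at 39.2 ± 1.76 against 1.92 ± 0.111 FPKM. In the other direction TIFY 5A (Cluster-10660.0), a jasmonate signalling repressor, stood at 0.33 ± 0.139 FPKM in sterile and 11.4 ± 1.24 in fertile buds, and WRKY70 (Cluster-1471.0), a regulator of salicylate and jasmonate defence, at 0.107 ± 0.101 against 3.67 ± 0.325 FPKM. The log2 fold changes, sterile over fertile, were 5.72 ± 0.11 for AS2, 4.28 ± 0.09 for MYB20, 4.19 ± 0.11 for LBD22, -5.23 ± 0.25 for TIFY 5A and -5.15 ± 0.38 for WRKY70 (± SE). Their adjusted p-values from edgeR's quasi-likelihood test were 7.1e-17, 2e-16, 1.68e-15, 8.54e-12 and 3.17e-09. In each of these clusters all 3 libraries of a clone lay apart from all 3 of the other, which the rule that named them required.

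Of 1380 regulator clusters tested, 786 passed an adjusted p of 0.05 in edgeR's test, 387 higher and 399 lower in the sterile clone, and 594 were not called. At a change of at least 2-fold, 79 were higher and 106 lower. The balance of directions moved with the scale. With the implied whole-library totals the median log2 fold change of all tested clusters shifted from 0.01 to 0.15 and the split became 567 higher and 296 lower. With limma on log2(FPKM + 1) of the same table it was 569 against 277. Changes below are relative to the regulators as a set, by TMM (trimmed mean of M-values) scaling, and no called change among the 80 clusters named by the rule fixed beforehand turned direction under a scaling or with a library left out. The replicates were bud samples of 1 clone per group with a biological coefficient of variation of 6.82%, so p-values measure the spread between these samples and not between sterile and fertile genotypes.

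Several regulators were near absent in 1 clone. ERF022 and a short cluster matching the splicing factor cef1 had 0 counts in all sterile libraries, which put them at least 37.1-fold and 32.5-fold lower than in fertile buds by a floor of 3 counts over the group. An AGL82 MADS-box cluster and FRS5 had 0 counts in all fertile libraries and were at least 33.6-fold and 22.9-fold higher in sterile buds by the same floor. DPBF3, an ABI5-like bZIP factor of abscisic acid response, had 1 count in the sterile and 599 in the fertile libraries, a ratio of 487 with a 95% counting interval of 87.1 to 19277. NFYB10, a subunit of the NF-Y complex, had 547 counts in the sterile and 3 in the fertile libraries, a ratio of 224 (interval 76.3 to 1090). The chloroplast factor MTERF6 was lower by a ratio of 117 (39.8 to 570) and the anthocyanin regulator MYB90 by 65.9 (11.5 to 2634). A B3-domain cluster matching At2g27410 was lower by 22.4 (5.91 to 189) and the cell-cycle factor MYB3R4 by 18.7 (4.89 to 159). A second AGL82 cluster was higher by 86.5 (29.2 to 423) and the iron-response factor ORG2 by 68.8 (11.9 to 2767). LBD2, at 11.1 ± 1.76 FPKM in sterile and 0.163 ± 0.0651 in fertile buds, was 57.3-fold higher by edgeR's fit to the counts. Floors and intervals cover counting error only. Names are those of the best Swiss-Prot hit, mostly from other species, and AGL82, TIFY 5A, WRKY70, LBD2 and LBD22 each named more than 1 cluster, among which reads could have been shared. Whether the alleles of the clones were assembled as separate clusters could not be checked for most of them.

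Jasmonate response regulators were lower in the sterile buds. In the list of stamen maturation and jasmonate factors, 14 of 22 clusters were lower, 2 were higher and 6 were not called, with a median log2 fold change of -0.89. Adjusted over the list alone, 16 were lower and 2 higher. The 9 lower members of the TIFY family (JAZ repressors of jasmonate response and their relatives) among them included TIFY 10B (Cluster-6671.9597), at 4.22 ± 0.361 FPKM in sterile and 58.4 ± 3.29 in fertile buds, and TIFY 9, at 5.93 ± 0.333 against 25.4 ± 2.58 (n = 3 each). A second TIFY 10B cluster, the most abundant, stood at 82.2 ± 2.25 against 211 ± 16.4 FPKM, and a second TIFY 5A cluster at 0.883 ± 0.67 against 13.2 ± 2.3. The log2 fold changes of these 4 clusters were -3.94 ± 0.09, -2.25 ± 0.10, -1.51 ± 0.07 and -4.01 ± 0.32, with edgeR adjusted p of 5.51e-16, 3.48e-12, 6.5e-12 and 3.83e-07. The jasmonate activators MYC2 (log2 fold change -1.19) and MYC4 (-1.37) and the repressor bHLH13 (-0.89) fell too. The 2 higher members, with Swiss-Prot names MYB2 (1.56) and MYB62 (0.38), match MYB24-like and MYB21 of Prunus mume, whose Arabidopsis namesakes act in stamen maturation. The list was called by camera with a preset correlation (adjusted p = 5.91e-05), and not with an estimated one (adjusted p = 0.459 with an estimated correlation). The Tify family as annotated by the authors gave 10 lower, 1 higher and 3 not called of 14 (camera adjusted p = 0.00277, and adjusted p = 0.967 with an estimated correlation).

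**Figure D1:**
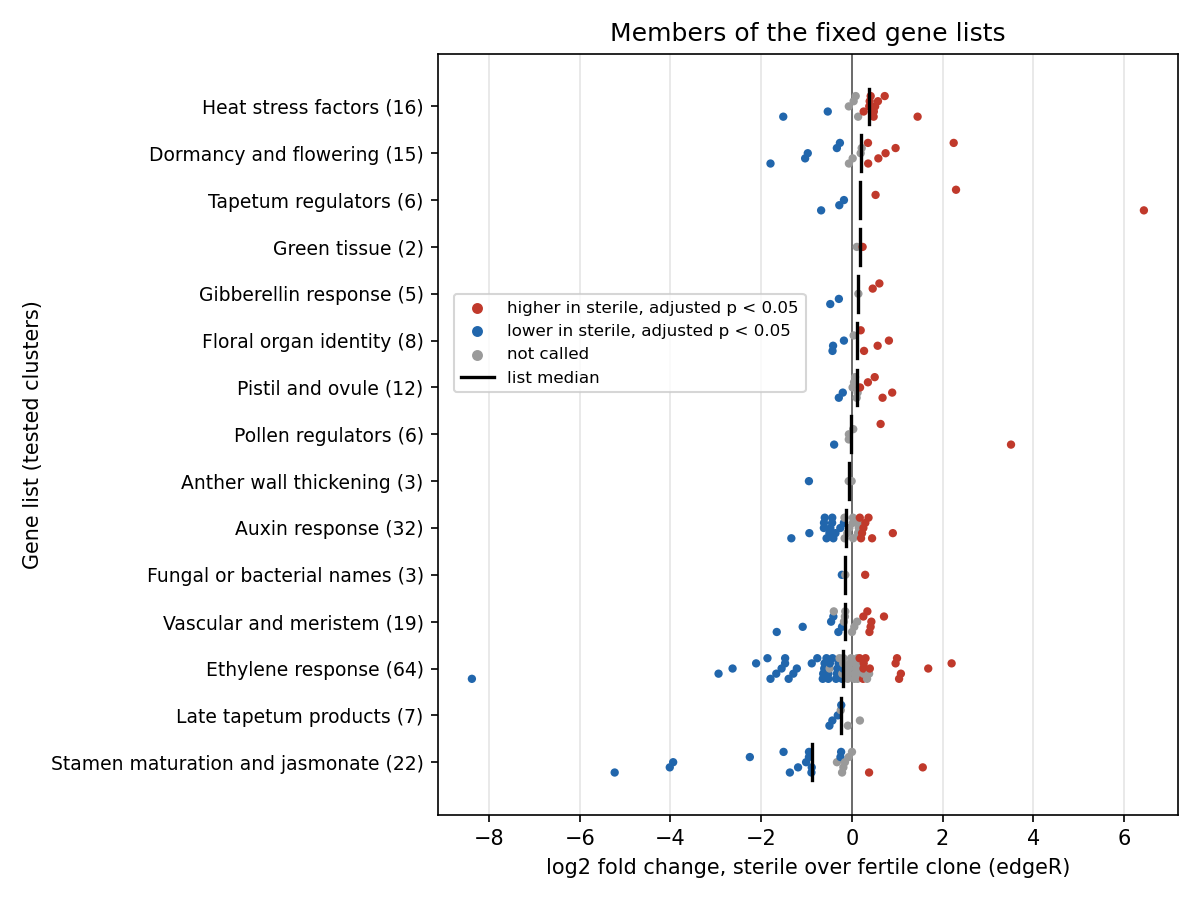
Each point is a tested cluster of a gene list fixed beforehand, placed by its log2 fold change (sterile over fertile, edgeR) and coloured by its call at an adjusted p of 0.05; black bars are list medians and the number of tested clusters stands beside each list (the fitted values of ERF022 and MS1, with 0 and 2 counts in a clone, depend on the prior count). The stamen maturation and jasmonate list lies to the left with a median of -0.89, and most other lists hold members on both sides of 0; the medians of the auxin, pollen and anther wall lists change sign with the implied whole-library totals.

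Tapetum regulators went both ways. The tapetum is the anther cell layer that feeds the developing pollen. Of the 6 tested clusters of that list 3 were higher and 3 lower (the same counts adjusted over the list alone), and the list as a whole was not called by camera (adjusted p = 0.578). MALE STERILITY 1 (MS1), a PHD-finger factor of late tapetum and pollen wall formation, was near absent from fertile buds, with 2 counts against 170, a ratio of 104.5 with a 95% counting interval of 28.5 to 870. bHLH10 (Cluster-6671.15380), a partner of DYT1 in tapetum development, stood at 135 ± 2.65 FPKM in sterile and 24.9 ± 0.87 in fertile buds, a log2 fold change of 2.30 ± 0.07 (edgeR adjusted p = 8.78e-15). Of a pair of clusters named ABORTED MICROSPORES (AMS), 1 was higher (0.52 ± 0.08) and 1 lower (-0.28 ± 0.06). MYB35 (TDF1), an early tapetum factor, was lower at -0.68 ± 0.13, with 3.07 ± 0.625 against 4.42 ± 0.292 FPKM. A second MYB35 cluster (32 counts in sterile, 12 in fertile buds) and a MYB80 cluster (20 and 13) fell below the low-count filter. Both had more counts in sterile buds, although the sterile libraries were smaller. MYB33 was at -0.18 ± 0.06, and its call was lost in 7 of 13 alternatives, namely DESeq2, 3 other library scales (-0.04 with the implied whole-library totals) and leaving out fertile replicate 2 (-0.14), sterile replicate 1 (-0.17) or sterile replicate 3 (-0.17). The call of the lower AMS cluster was lost with the implied whole-library totals (-0.14). Without fertile replicate 1 the list passed the camera test (adjusted p = 0.0184, the lowest of its alternatives). The highest, from all libraries, was adjusted p = 0.759 with an estimated correlation.

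Other anther and pollen genes showed mixed directions as well. MYB26, needed for wall thickening of the anther and for dehiscence, stood at 12.6 ± 1.2 FPKM in sterile and 21.9 ± 0.767 in fertile buds (log2 fold change -0.95 ± 0.08, edgeR adjusted p = 2.29e-08). Both clusters of the wall factor MYB83, at 1.02 to 1.47 FPKM, were not called, at -0.07 ± 0.30 and -0.01 ± 0.24. This left 1 of 3 members of the anther wall list lower (camera adjusted p = 0.578, and 1 lower adjusted over the list alone). The list did not hold the anther wall factor NAC043 (NST1), of which 1 cluster stood lower in sterile buds (given below with the NAC factors). Among 6 pollen regulators 2 were higher, 1 lower and 3 not called (the same adjusted over the list alone; camera adjusted p = 0.758), or 3 higher and 0 lower with the implied whole-library totals. A cluster named MYB101 by Swiss-Prot and MYB51-like by its nucleotide hit rose by 3.51 ± 0.18, the pollen MADS factor AGL65 by 0.63 ± 0.15, and WRKY2 was lower at -0.39 ± 0.11, a call lost with the implied whole-library totals (-0.26). A second MYB101 cluster, at 36.1 ± 1.35 and 34.3 ± 2.65 FPKM, was not called. The list's median was -0.02 and its mean 0.61.

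The floral organ identity genes in the list moved by small amounts. None of them had APETALA3, PISTILLATA or AGAMOUS itself as best Swiss-Prot hit, so these stamen identity genes were not covered. Of 8 tested clusters 4 were higher, 3 lower and 1 not called, with the same counts adjusted over the list alone and a camera adjusted p of 0.774. A FRUITFULL-type cluster (AGL8 homolog) stood at 51.4 ± 2.53 FPKM in sterile and 31.3 ± 1.73 in fertile buds (log2 fold change 0.57 ± 0.07), and the SEPALLATA-type CMB1 at 7.61 ± 0.766 against 3.91 ± 0.167 (0.82 ± 0.12). The SEPALLATA3-type FBP2 was lower at -0.41 ± 0.08 and MADS6 at -0.43 ± 0.07. MADS14 rose by 0.27 ± 0.07. The call of ULTRAPETALA 1 (0.19 ± 0.06), matched by its name and not a MADS gene, was lost without fertile replicate 2 (0.17), sterile replicate 2 (0.16) or sterile replicate 3 (0.17). SEPALLATA 1, at 113 ± 3.35 and 114 ± 7.52 FPKM (-0.18 ± 0.07), lost its call in 6 of 13 alternatives, namely 3 other library scales (-0.04 with the implied whole-library totals), the replicate block and leaving out sterile replicate 1 (-0.16) or sterile replicate 3 (-0.18). EJ2 was not called. In the pistil and ovule list 5 of 12 were higher, 2 lower and 5 not called (likewise adjusted over the list alone; camera adjusted p = 0.333), and with the implied whole-library totals 7 were higher and 0 lower. DROOPING LEAF, which matches CRABS CLAW of Prunus mume and acts in carpel formation, stood at 69.9 ± 0.702 against 34 ± 1.89 FPKM (0.89 ± 0.07, edgeR adjusted p = 6.32e-09). The ovule identity gene AGL11 rose by 0.68 ± 0.15, and the BEL1-like factors BLH9 and BLH7 by 0.50 ± 0.08 and 0.35 ± 0.07.

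Bud dormancy and cold-response factors also split, with 6 higher, 5 lower and 4 not called of 15 (the same adjusted over the list alone; camera adjusted p = 0.816). The dormancy-related MADS factor SVP was lower at 3.37 ± 0.116 against 5.96 ± 0.575 FPKM (log2 fold change -0.97 ± 0.12), and a second SVP cluster was higher (0.36). DREB3, a dehydration-response factor, was lower at 14.7 ± 0.261 against 45.9 ± 3.33 FPKM (-1.79 ± 0.08), while DREB2B rose by 2.24 ± 0.23 and the flowering MADS factor AGL42 by 0.74 ± 0.11.

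Among ethylene response factors 30 of 64 clusters were lower, 12 higher and 22 not called, the same adjusted over the list alone. The list was not called by camera (adjusted p = 0.187), and with the implied whole-library totals the counts were 26 lower and 19 higher. ERF003 fell by 1.55 ± 0.09 on the log2 scale and ERF5 by 1.39 ± 0.08, while ERF071, a hypoxia-related factor, rose by 2.20 ± 0.07, from 41.9 ± 3.05 FPKM in fertile to 214 ± 7.77 in sterile buds (edgeR adjusted p = 4.81e-14). A second ERF5 cluster, at 19.9 ± 1.58 FPKM in sterile and 20.2 ± 2.05 in fertile buds, was not called (-0.19). A second ERF003 cluster, with 9 counts in sterile and 3 in fertile buds, fell below the low-count filter. Heat stress factors were more often higher, with 10 higher, 2 lower and 4 not called of 16 (likewise adjusted over the list alone), and the list missed the camera threshold (adjusted p = 0.265). HSF30 rose by 1.45 ± 0.11 and HSFA1 by 0.57 ± 0.08, and HSFB3 and HSFC1 were lower at -1.51 ± 0.12 and -0.53 ± 0.08. Of 32 auxin response clusters 14 were lower, 8 higher and 10 not called, and 14 lower and 9 higher adjusted over the list alone (camera adjusted p = 0.492). With the implied whole-library totals the balance turned to 11 lower and 12 higher. The auxin repressors IAA4 (-1.33 ± 0.14), IAA8 (-0.62 ± 0.06) and IAA9 (-0.50 ± 0.06) and ARF17 (-0.56 ± 0.07), whose Arabidopsis namesake acts in pollen wall formation, were lower. The gibberellin list had 2 higher, 2 lower and 1 not called of 5 (the same adjusted over the list alone; camera adjusted p = 0.816). In it the DELLA repressor GAI was named by 1 higher (0.46 ± 0.06) and 1 lower cluster (-0.48 ± 0.07), GAIPB was lower (-0.29 ± 0.06) and SCL3 rose by 0.61 ± 0.14.

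Camera called none of the vascular, late tapetum product and fungal or bacterial lists, and the green tissue list was too small to test. The vascular and meristem list had 6 higher, 6 lower and 7 not called of 19 (the same adjusted over the list alone; camera adjusted p = 0.816), or 7 higher and 3 lower with the implied whole-library totals, with KNAT6 up by 0.71 ± 0.08, a KNOTTED-like factor 2 cluster up by 0.39 ± 0.07, and PHL11 and WOX1 lower at -1.66 ± 0.13 and -1.08 ± 0.14. The green tissue list had 2 tested clusters, GLK2 (0.11 ± 0.09, not called) and a cluster named LHCB4.3 (0.24 ± 0.08) that the authors class as a high mobility group regulator. The latter lost its call without fertile replicate 2 (0.19), fertile replicate 3 (0.18), sterile replicate 2 (0.19) or sterile replicate 3 (0.23). The late tapetum product list had 4 lower and 3 not called of 7, the same adjusted over the list alone (camera adjusted p = 0.297). It caught general regulators by name (GRP-2, GATA9, NFYA9 and IAA9) and no tapetum product, with GRP-2 at -0.31 ± 0.06, GATA9 at -0.43 ± 0.13 and NFYA9 at -0.23 ± 0.07, whose call was lost with the implied whole-library totals (-0.10) and without sterile replicate 1 (-0.17). The list of pollen wall enzymes matched 0 clusters, since the named table holds regulators. Of 20 clusters with fungal or bacterial best-hit names 3 were tested, 1 higher, 1 lower and 1 not called, and adjusted over the list alone 2 were lower (camera adjusted p = 0.816). These were conserved proteins with yeast names, namely spp27 clusters at 0.29 ± 0.07 and -0.22 ± 0.07, the latter not called with the implied whole-library totals with (-0.16) or without (-0.08) median ratios, and rhp16 at -0.15 ± 0.07.

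Of 61 transcription factor families tested, Tify alone passed camera with the preset correlation, and 0 passed with an estimated one, where camera also gave 0 families an unadjusted p under 0.05, while fry called 35. The LOB family came next, with 13 higher, 4 lower and 7 not called of 24 (adjusted p = 0.113), followed by the CONSTANS-like family with 4 higher and 2 not called of 6 (adjusted p = 0.147). COL6 rose by 0.99 ± 0.10 and COL13 by 0.75 ± 0.08. Without fertile replicate 1 the LOB family passed as well (adjusted p = 4.99e-06, the lowest of its alternatives). The highest, from all libraries, was adjusted p = 0.967 with an estimated correlation. Of the 14 lists tested, fry of limma, which does not compare a list with other genes, called 10, all except the floral organ identity, dormancy, vascular and fungal or bacterial lists.

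Differences between the clones were also wide among clusters without names. Of 21730 clusters with at least 1 FPKM in at least 3 libraries, limma on log2(FPKM + 1) called 10816, or 49.8%, with 6320 higher and 4496 lower in the sterile clone. Scaling each library to the same median turned this split to 4671 higher and 5712 lower. Calls were made for 756 of 1339 regulators here and for 10060 of 20391 other clusters. With a change of at least 2-fold on that scale, 1481 were higher and 1343 lower. The files do not pair the clusters other than regulators with names, and the 4 clusters that follow are among these. The changes of Cluster-6671.1441 and Cluster-6671.20011 were 8.15 ± 0.10 and 6.62 ± 0.07 on the log2(FPKM + 1) scale, with 675 ± 10.0 and 541 ± 50.8 FPKM in sterile against 1.4 ± 0.376 and 4.5 ± 0.231 in fertile buds. Cluster-6671.10134 and Cluster-6671.7999 changed by -6.14 ± 0.13 and -6.12 ± 0.14, from 363 ± 39.4 and 259 ± 11.2 FPKM in fertile to 4.17 ± 0.779 and 2.79 ± 0.733 in sterile buds. At 1 FPKM or more in every library of 1 clone and 0 in every library of the other, 219 clusters were listed in the sterile clone only and 214 in the fertile clone only.

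The authors' deposited table marked 90 regulator clusters as up and 97 as down in the sterile clone. Of these, 85 and 90 were tested here, and all of them were called in the same direction by edgeR. Every call in the authors' deposited table had an absolute log2 fold change of at least 1.00 and a q of at most 0.0461. Across clusters, which are not independent replicates, the log2 fold changes of the authors' deposited table correlated with edgeR's at r = 0.999. The authors' values lay 0.069 above edgeR's at the median, an offset that a correlation does not see. At a q under 0.05, without a fold minimum, their balance was 389 higher and 288 lower, against 387 and 399 by edgeR's adjusted p.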

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

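The count of 786 called regulators came to 716 to 863 under the other tests, scales and filters tried. With single libraries left out 686 to 765 of these calls were kept, and the highest count was 906, without fertile replicate 1. The FPKM table gave 8092 to 11127 calls with a library left out against 10816. Requiring a change of at least 2-fold left 185 regulators and 2824 clusters of the FPKM table, by construction. An estimated correlation left 0 families and 0 lists (camera gave 0 families and 1 list, the jasmonate list, an unadjusted p under 0.05), and fry, which does not compare a set with other genes, called 35 families and 10 lists. Leaving out single libraries gave 1 to 2 families and 1 to 2 lists, and without fertile replicate 1 the 2 families were Tify and LOB and the 2 lists the jasmonate and tapetum lists. The scale moved the balance of directions, and implied whole-library totals raised the median of all tested regulators to 0.15. Of 1040 values of the 80 named clusters under alternatives, 997 kept direction and call, 26 lost the call, 13 of them with a library left out and 6 with implied totals, all with log2 fold changes of 0.26 or less in size, and 6 gained it. The other 11 changed sign, none of them called in the main test. MYB83 Cluster-10490.0 was 0.064 with implied totals and -0.455 to 0.126 with a library left out. The value of MYB83 Cluster-6671.14231 was 0.0383 with table totals, 0.13 with implied totals, 0.0535 with implied totals and median ratios, and -0.109 to 0.0696 with a library left out. MYB101 Cluster-6671.8436 was 0.0668 with implied totals, and EJ2 Cluster-6671.11539 was -0.0065 to 0.0971 with a library left out. The cause of these changes was not tested. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.00147, 0.00223 and 0.0117, and 1 of 3 fertile libraries correlated best with its own number. A replicate block gave 781 regulators, 10000 clusters of the FPKM table, 1 family and 1 list. Depth limits low clusters, since 3 counts at median length stand for 0.0737 to 0.0864 FPKM in the sterile libraries.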

Other observations

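The choice of families and genes in these paragraphs, and the tests of library scale, rapid stress response, anther share and partners by Swiss-Prot name, were made after the results were seen. Members of the LOB family, which was not called by camera (adjusted p = 0.113), went both ways. LATERAL ORGAN BOUNDARIES stood at 16.1 ± 0.982 FPKM against 6.63 ± 0.403 in fertile buds (n = 3 each), LBD4 at 3.69 ± 0.565 against 1.06 ± 0.299, and a second LBD22 cluster at 1.68 ± 0.0379 against 0.347 ± 0.195. The 4 lower clusters were named LBD36 (0.767 ± 0.0961 against 2.93 ± 0.174 FPKM), LBD15 (log2 fold change -1.47), LBD27 (-0.99) and LBD19 (-0.80). A second LBD36 cluster, at 6.71 ± 1.23 against 5.5 ± 0.342 FPKM, and a second LBD15 cluster were among the 7 not called. The nitrogen-response members LBD37 and LBD38 had log2 fold changes of 0.43 and 0.58.

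Among WRKY factors, many of which act in defence, 24 of 45 clusters were lower, 9 higher and 12 not called, and the family was not called by camera (adjusted p = 0.412). With the implied whole-library totals 20 were lower and 14 higher. WRKY18 stood at 3.18 ± 0.0346 FPKM in sterile and 17.4 ± 0.59 in fertile buds, a second WRKY70 cluster at 1.64 ± 0.311 against 19.9 ± 2.84, and WRKY24 at 2.65 ± 0.237 against 10.6 ± 1.41. WRKY35, WRKY28 and WRKY14 were higher, with log2 fold changes of 1.33, 1.33 and 0.93, and a second WRKY28 cluster was lower (-0.89). Dof factors were more often higher, 13 of 25 against 6 lower, with a camera adjusted p of 0.48, and included DOF5.3 (1.11), DOF1.5 (2.17) and 1 CDF2 cluster (1.12), while another CDF2 cluster was not called (0.15). Of 65 NAC clusters 24 were higher, 18 lower and 23 not called (camera adjusted p = 0.73), and 33 were higher and 13 lower with the implied whole-library totals. A cluster named NAC072, a dehydration and abscisic acid response gene, stood at 18.5 ± 1.33 against 5.75 ± 0.775 FPKM, and a more abundant NAC072 cluster, at 56.4 ± 1.27 against 54.1 ± 2.86 FPKM, was not called. A cluster named NAC043 (NST1), a factor of secondary wall thickening in anthers, stood at 1.74 ± 0.359 against 6.56 ± 0.68 FPKM, and a second NAC043 cluster was not called (-0.77).

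The jasmonate list was lower in the sterile buds under each of the 5 library scalings, with medians no higher than -0.75, which argues against scaling as the source. Handling that differed from sample to sample should widen the spread within a clone. The list's spread was 1.07 times that of clusters matched on expression (bootstrap interval over list members 0.851 to 1.17), so little widening was seen in these libraries. Members that respond together are not independent, and the interval does not cover the uncertainty from 3 libraries per clone. Uneven handling is therefore not excluded. A wider stress response of the fertile buds at collection, by wounding or time of day, may underlie the pattern and cannot be told apart from a genetic difference, with 1 clone per group. Of 26 rapid stress response clusters outside the list (17 of 30 names looked for, 7 clusters shared with the ethylene list) 18 were lower and 3, ZAT12 (2.08) among them, higher. Their median was -0.63, and its bootstrap interval over clusters, of -1.39 to -0.23, spans the -0.5 or lower that this explanation needs.

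Of the 32 regulators changed by at least 8-fold, 30 had a nucleotide best hit. In 0% of these did another cluster with the same hit move by at least 2-fold in the opposite direction. Alleles of 1 locus assembled as separate clusters for each clone would give such partners. Of the 30, however, only 1 shared its hit with any other tested cluster, so the rest could not have shown such a partner. Partners without a name could not be searched. Split alleles and a difference in expression therefore cannot be told apart here. By Swiss-Prot name, which also joins paralogs, 3 of the 32 had an opposite partner and 9 a partner in the same direction. Genes lost or silenced in 1 clone remain possible and were not tested, nor were the unnamed clusters listed in 1 clone only.

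MS1 and bHLH10 were higher in the sterile buds. A larger share of anther tissue would raise the other tapetum genes by about as much as bHLH10 (2.30). The 4 other tapetum clusters with at least 100 counts in each clone had a median log2 fold change of -0.23 (from -0.68 to 0.52), so these did not rise as bHLH10 did. MS1 and bHLH10 had been singled out as the highest of the list, so the others lay lower by selection. Under 1 shared shift, however, selection would leave gaps of about the size of the errors. The highest of the 4 stood at 0.52 ± 0.08 and bHLH10 at 2.30 ± 0.07 (± SE). Left out by the count minimum were a second MYB35 cluster (32 counts in sterile, 12 in fertile buds) and a MYB80 cluster (20 and 13). Both of these had more counts in sterile buds. For the 4 clusters the values argue against anther share as the only source of the rise of bHLH10. A smaller part played by anther share stays open, as do a later anther stage of the sterile buds and an effect of the clone's genotype. The order of MS1 and MYB35 had prompted the stage reading, so no value here tests it.

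The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 786 regulators and 10816 clusters of the FPKM table, and the highest of the other 9 splits gave 0 in both. For families the real split gave 1 and the highest other 10, and 9 of the 10 splits gave at least 1. Every other split still sets 2 libraries of 1 clone and 1 of the other against the rest, and what its family calls come from was not tested. For lists the real split gave 1 and the highest other 2, and 7 of the 10 splits gave at least 1.

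In the 17 regulator clusters with bacterial best hits, all below the low-count filter, summed counts per library were 22 to 40 in fertile and 14 to 23 in sterile buds, or 17.7 to 31.1 and 12.5 to 23.0 CPM of the regulator table, ranges that overlap.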
